A study of Homo sapiens with 6 samples.

How the data were processed

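The series holds RNA sequencing of Panc-1 cells, a human cell line from a pancreatic ductal carcinoma. Cells treated with fisetin, a plant flavonol, were compared with untreated control cells, with 3 libraries in each group. The dose and the duration of the treatment are not given in the sources used here. Groups and replicate numbers come from the sample titles. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

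Per the labels' protocols, RNA was extracted with Trizol and libraries were built with an NEBNext Ultra kit for Illumina sequencing. Per the submitters' processing notes, bcl2fastq, Bowtie2 2.2.3 and HTSeq 0.6.0 were used with build hg38, with no roles or settings stated. The annotation and the strand setting are not given in the sources used here, so reads of overlapping genes and of antisense partners cannot be separated, and members of families of near-identical genes and pseudogenes may share reads. The deposited values are RPKM, reads per kilobase of exon scaled to the total of reads assigned to genes, with no statement of whether reads or read pairs were counted. This unit was worked out from the values. Each table held the same 30446 gene identifiers, and no gene was at 0 in all 6 libraries. Gene symbols, types and coordinates were taken from GENCODE 29 (build hg38), which held 30315 of the identifiers. The other 131 have no name here.

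With exon lengths from GENCODE 29, between 94.3% and 94.5% of the values above 0 in each library came out as a whole number of reads, within 0.02 of a read. The read totals recovered in this way were 17214962, 17825783 and 17725412 for fisetin replicates 1, 2 and 3 and 17358744, 17314633 and 17579824 for control replicates 1, 2 and 3. They show the depth, and the recovered reads entered the chi-square comparison of libraries, the shares of mitochondrial reads, the simulation, the TMM factors and the limma-voom alternative, but not the main test. Totals differed little between groups, so depth limits all libraries alike, and genes near 1 RPKM carry the largest counting error.

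The design chosen before the data were examined assumed read counts. The deposited values are not counts, so the test it named for normalized values was used. This was limma 3.58.1 with an intensity trend on log2(RPKM + 1), run in R 4.3.3, on genes with a value of at least 1 in at least 3 libraries, with the group as the single term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. A log2 fold change on this scale understates the change of genes with low values. Folds given beside it are ratios of mean RPKM. Counts of genes changed at least 2-fold instead use the log2 fold change of the fit, at least 1 in either direction. The deposited scaling to the total of each library was kept, and median-of-ratios, TMM and upper-quartile scaling were computed as alternatives.

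A total of 37 gene lists were fixed before the data were examined, and 33 of them had at least 5 tested members. They cover autophagy, the lysosome, stress responses, mitochondria, cell cycle, lipid and glucose metabolism, signalling, ribosomes, proteasome, histones, DNA repair and markers of other cell types. Each was tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The estimated form tests on the few residual degrees of freedom of the libraries, so its p is larger even at the same correlation. Members were counted by their adjusted p over all tested genes and adjusted over the list alone.

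Named genes follow a rule also fixed before the data were examined. It takes the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among called genes with a mean of at least 10 RPKM in the higher group, no overlap between the groups and a standard symbol. It adds 20 genes named in advance, and up to 4 members of each list with the smallest p (the 2 most abundant members where fewer than 2 passed). The rule's minimum was written for depth-scaled read counts and was applied to RPKM.

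The procedure was tested on simulated reads for the comparison of fisetin with control, drawn from the means and spread of these libraries with 50 genes changed at each size. Over 12032 genes, limma called 0 of 50 genes changed 1.5-fold, 12 of 50 changed 2-fold, 33 of 50 changed 3-fold and 40 of 50 changed 4-fold, and 4 unchanged genes. The simulation drew genes independently and changed far fewer than the 3929 called in the real data. Fewer changed genes make the adjusted p stricter, so these shares do not give the sensitivity of the real test.

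Alternatives were a stricter and no filter on low values, pseudocounts of 0.5 and 0.1, limma-voom on the recovered reads, other scalings, a replicate block, each library left out in turn, an adjusted p under 0.01, a test against a 1.5-fold change, array weights, and removal of each library's trend on GC content and exon length. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 prepared the tables, and matplotlib 3.10.9 drew the plots. Genes below the filter were left out of the tests. The values of some genes that the rule names are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.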

Results

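Transcript levels were measured in 6 libraries of Panc-1 cells, 3 treated with fisetin and 3 untreated. The recovered depth was 17214962 to 17825783 reads per library with fisetin and 17314633 to 17579824 in the control group. Pearson's r of log2(RPKM + 1) across genes was 0.978 to 0.989 between fisetin libraries and 0.988 between control replicates 1 and 2. Control replicate 3 stood apart from them, with r of 0.927 and 0.897, while pairs of a fisetin and a control library gave 0.84 to 0.925. Genes are not independent replicates, so these correlations describe the libraries only. Reads from mitochondrially encoded genes made up 8.63% of control replicate 3, against 6% and 5.65% in control replicates 1 and 2 and 4.3% to 4.98% with fisetin. No pair of libraries agreed within sampling noise, the lowest chi-square of the recovered reads being 9.2 per gene, between fisetin replicates 1 and 2.

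**Figure D1:**
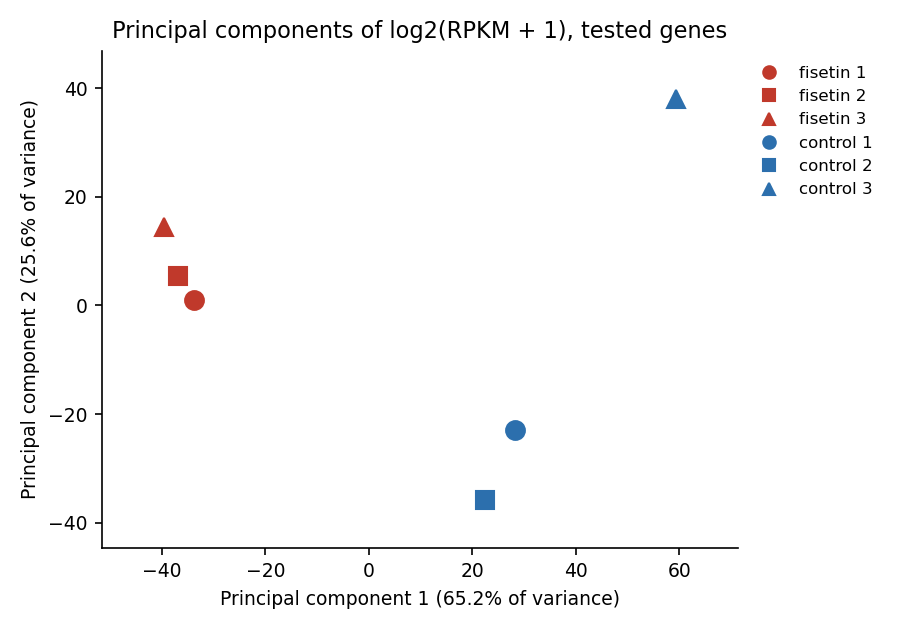
Principal components 1 and 2 of log2(RPKM + 1) over the tested genes, 1 point per library, with colour for the group and marker for the replicate. The fisetin libraries lie at -39.6 to -33.8 on component 1 and the control libraries at 22.5 to 59.4, with control replicate 3 away from both other controls.

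The series title frames the comparison as a question of how fisetin acts on autophagy through stress of the endoplasmic reticulum (ER) and of mitochondria. With fisetin, 33 of 43 tested genes of the integrated stress response rose and 2 fell (adjusted p = 0.2 with an estimated correlation), ATF3, SESN2 and TRIB3 among the risen, and the haem oxygenase gene HMOX1 and the autophagy gene MAP1LC3B also rose. Of 23 genes of cholesterol synthesis and uptake 14 fell and 0 rose (adjusted p = 0.0804 with an estimated correlation), and of 18 genes of fatty acid synthesis 6 fell and 1 rose (adjusted p = 0.2 with an estimated correlation), with SCD, FASN and SREBF1 lower. Of 40 mitotic genes 11 fell and 1 rose (adjusted p = 0.313 with an estimated correlation), such as KIF20A and CCNB1, and of 13 mitochondrially encoded genes 7 fell and 0 rose (adjusted p = 0.2 with an estimated correlation), such as MT-CO3. ATF3 (ENSG00000162772, hg38 chromosome 1 at 212565334 to 212620777) went from 1.06 ± 0.528 RPKM in control to 57.8 ± 3.62 RPKM with fisetin (SD, n = 3 each), and SCD (ENSG00000099194) from 489 ± 115 RPKM to 43.6 ± 8.26 RPKM.

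Of 12396 genes tested, 3929 (31.7%) changed by limma, 2758 higher and 1171 lower with fisetin. Of these 1384 changed at least 2-fold by the log2 fold change (860 higher, 524 lower). This count leaves out called genes with low values whose RPKM ratio is larger, such as IFIT1, 4.53-fold lower at a log2 fold change of -0.976. The 2 groups did not overlap in 3928 of the 3929, and in 52.6% of all tested genes, where chance gives 10%. The median log2 fold change over all tested genes was 0.20 on the deposited scale, and list medians below are given relative to it. With median-of-ratios scaling that median was 0.01 and the split was 1535 higher and 1680 lower, with 2706 calls shared with the deposited scaling. The count was 6402 without control replicate 3, and 1896, 1651, 1907 and 2183 without fisetin replicates 1, 2 and 3 and control replicate 1. Of 142 genes named by the rule, 130 were called, and 28, 31 and 27 of these were no longer called without fisetin replicates 1, 2 and 3, 24, 13 and 0 without control replicates 1, 2 and 3, and 15 with median-of-ratios scaling.

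Among the 12 genes with the largest rise, ATF3, TRIB3, DDIT3, PPP1R15A and SESN2 are known targets of the transcription factor ATF4. SESN2 (ENSG00000130766) rose from 5.45 ± 0.685 to 93 ± 5.11 RPKM (17.1-fold, log2 fold change 3.87, SE 0.14, limma adjusted p = 0.00019), and TRIB3 from 9.24 ± 2.2 to 142 ± 2.92 RPKM (15.3-fold). HMOX1, on chromosome 22 at 35380361 to 35394214, encodes an enzyme that degrades haem and rose 13.4-fold to 378 ± 35 RPKM. RAB39B, a small GTPase, rose 14.9-fold and LAMP3, a lysosomal membrane protein, 12.2-fold. GADD45A rose 10.1-fold and DUSP5, a phosphatase of MAP kinases, 9.49-fold. NGFR rose 12.4-fold and BEX2 15.8-fold, and control replicate 3 moved both folds by over 1.5 times, with NGFR at 5.36 RPKM there against a mean of 0.695 in the other controls and BEX2 at 1.79 against 0.245 RPKM.

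The 12 genes with the largest fall included the lipid genes SCD, FASN, SREBF1 and FADS2. The desaturase gene SCD was 11.2-fold lower with fisetin (log2 fold change -3.45, SE 0.22, limma adjusted p = 0.000486). FASN was 8.6-fold lower, FADS2 10.1-fold lower and SREBF1, which encodes a regulator of lipid synthesis, 12.2-fold lower. SREBF1 stood at 103 RPKM in control replicate 3 and at a mean of 27.3 RPKM in the other controls, and VWA1 at 139 and 52.3 RPKM. The surface protein gene CD24 was 11.7-fold lower, COL1A1 11.7-fold, the tubulin gene TUBA4A 19.3-fold, the Wnt receptor gene FZD2 13.9-fold, VWA1 11.4-fold, B4GALNT4 12.1-fold, B3GNT7 9.51-fold and PLCH2 14.7-fold. CD24 and TUBA4A belong to families with near-identical copies, and their values may hold shared reads.

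**Figure D2:**
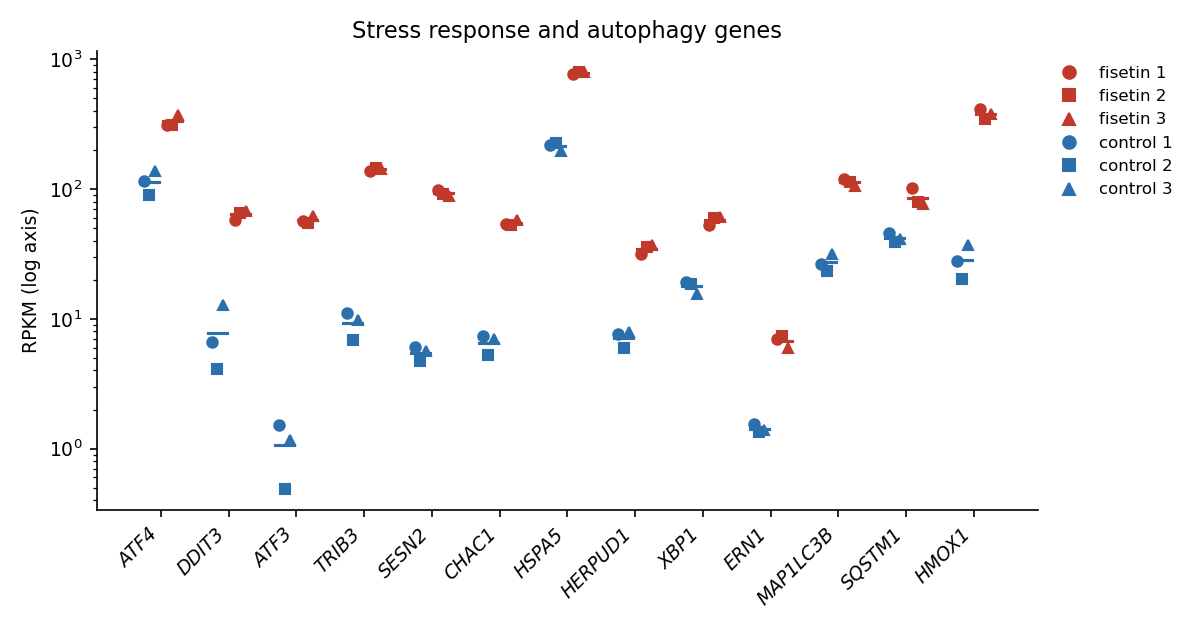
RPKM on a log axis of 13 stress response and autophagy genes in each library, with colour for the group, marker for the replicate and a line at the group mean (n = 3 each). The groups do not overlap for any of them, with HSPA5 at a mean of 787 RPKM with fisetin and 213 RPKM in control.

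Of 43 tested genes of the integrated stress response, which slows general translation and raises ATF4, 33 rose and 2 fell over all genes, and 35 rose and 2 fell adjusted over the list alone. The list's median lay 1.06 above that of all genes, with a camera adjusted p = 5.2e-11 and an adjusted p = 0.2 with an estimated correlation. ATF4 (ENSG00000128272), on chromosome 22 at 39519695 to 39522685, rose from 114 ± 23.5 to 331 ± 32.8 RPKM (limma adjusted p = 0.00247). DDIT3, which encodes the stress-induced factor CHOP, rose from 7.84 ± 4.48 to 63.7 ± 5.19 RPKM, and CHAC1, an enzyme that degrades glutathione, rose 8.36-fold. ALDH18A1 and PSPH, of amino acid synthesis and chosen after their values were seen, were the members that fell, and 0 fell without fisetin replicate 2 or 3 and 1 without fisetin replicate 1, control replicate 1 or control replicate 2. NUPR1 rose from 0.623 ± 0.27 to 2.15 ± 0.901 RPKM (limma adjusted p = 0.0283), and its adjusted p was 0.0513 with median-of-ratios scaling.

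Among 45 ER chaperone and ER-associated degradation genes, 15 rose and 1 fell, with 17 and 3 adjusted over the list alone. The camera adjusted p was 0.128. The ER chaperone gene HSPA5, on chromosome 9 at 125234853 to 125241330, rose 3.7-fold to 787 ± 18.9 RPKM (log2 fold change 1.88, SE 0.13), and HERPUD1, which acts in ER-associated degradation, rose 4.85-fold. XBP1 rose 3.26-fold, as total transcript with no view of its splicing. The count of risen members was 22 without control replicate 3, 9, 7, 7 and 8 without fisetin replicates 1, 2 and 3 and control replicate 1, and 8 with median-of-ratios scaling, where 4 fell. The fallen member was PDIA4, chosen after its values were seen, and 5 fell without control replicate 3, 3 without control replicate 2 and 0 without control replicate 1 or any 1 of the fisetin libraries.

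Of 17 sensors and adaptors of the unfolded protein response, 6 rose and 0 fell over all genes, and 7 rose adjusted over the list alone (camera adjusted p = 0.11). The sensor genes ERN1 and ATF6 rose 4.74-fold and 3.31-fold. The kinase gene MAPK8 rose 2.19-fold and DELE1, which relays mitochondrial stress, 1.65-fold. EIF2AK3, the gene of the sensor PERK, stood at 5.17 ± 0.76 with fisetin and 3.1 ± 1.11 RPKM in control (limma adjusted p = 0.0835, and 0.042 without control replicate 3). Without any 1 of the fisetin libraries the count of risen members was 3, and 1 fell without control replicate 3 or with median-of-ratios scaling. DELE1 had an adjusted p of 0.0566 with median-of-ratios scaling.

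Of 35 tested genes of the core autophagy machinery, 15 rose and 0 fell over all genes, and 20 rose adjusted over the list alone. The median lay 0.41 above that of all genes (camera adjusted p = 0.000682, adjusted p = 0.2 with an estimated correlation). MAP1LC3B, which encodes the autophagosome protein LC3B, on chromosome 16 at 87383995 to 87404779, rose from 27.2 ± 4.18 to 113 ± 6.84 RPKM (log2 fold change 2.02, SE 0.15, limma adjusted p = 0.000795). The kinase gene ULK1 rose 2.14-fold, ATG101 2.17-fold and TMEM41B 2.15-fold, while BECN1 stood at 6.35 ± 0.304 with fisetin and 4.67 ± 0.641 RPKM in control (adjusted p = 0.0854). The count was 25 without control replicate 3, and with median-of-ratios scaling 12 rose and 1 fell.

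Of 23 autophagy receptors and mitophagy genes, 11 rose and 0 fell by either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.0617, and 0.0425 without fisetin replicate 2). The receptor gene SQSTM1 rose 2.04-fold to 85.7 ± 14.3 RPKM, NBR1 2.49-fold, TOLLIP 2.15-fold and OPTN 1.89-fold. PINK1, a kinase that marks damaged mitochondria, stood at 2.49 ± 0.183 with fisetin and 1.9 ± 0.739 RPKM in control (limma adjusted p = 0.291, and 0.0112 without control replicate 3). BNIP3 stood at 30.9 ± 3.67 with fisetin, 90.7 RPKM in control replicate 3 and a mean of 30.1 RPKM in the other controls. The count was 6, 7, 5 and 7 without fisetin replicates 1, 2 and 3 and control replicate 1, and with median-of-ratios scaling 7 rose and 1 fell. Without control replicate 2 or 3, 1 fell.

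Among 37 lysosomal genes, 18 rose and 0 fell over all genes and adjusted over the list alone. The median lay 0.26 above that of all genes (camera adjusted p = 0.00699, adjusted p = 0.335 with an estimated correlation). The proton pump gene ATP6V0A1 rose 2.65-fold, the sialidase gene NEU1 2.36-fold and the cholesterol transporter gene NPC1 2.64-fold. TFEB, a regulator of lysosomal genes, stood at 1.61 ± 0.303 with fisetin and 1.89 ± 0.102 RPKM in control (limma adjusted p = 0.443). The count was 10, 9, 10 and 10 without fisetin replicates 1, 2 and 3 and control replicate 1, and 10 with median-of-ratios scaling.

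Of the 13 mitochondrially encoded protein genes, 0 rose and 7 fell over all genes, and 8 fell adjusted over the list alone. The median lay at -0.86 relative to all genes (camera adjusted p = 8.74e-06, adjusted p = 0.2 with an estimated correlation). MT-CO3 was 2.46-fold lower with fisetin, MT-CO2 2.01-fold, MT-ATP6 1.86-fold and MT-ND1 1.6-fold. The count was 4, 2, 4 and 4 without fisetin replicates 1, 2 and 3 and control replicate 1. Control replicate 3 lay 0.21 above the other controls in the median of this list.

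Among 56 nuclear-encoded subunits of oxidative phosphorylation, 1 rose and 3 fell over all genes and 0 adjusted over the list alone. The list lay at -0.27 relative to all genes (camera adjusted p = 0.0112, adjusted p = 0.769 with an estimated correlation), and the call was lost without control replicate 3 (adjusted p = 0.638), where the list lay at -0.02 relative to all genes and 10 rose and 4 fell. With median-of-ratios scaling 0 rose and 6 fell. Without fisetin replicates 1, 2 or 3 0 rose and 0 fell, and without control replicate 1, 0 rose and 1 fell, and 0 rose without control replicate 2. NDUFB10 was 2.61-fold lower, SDHA 1.51-fold and ATP5F1A 1.36-fold, while NDUFB5 rose 1.41-fold (limma adjusted p = 0.0442, and 0.217 with median-of-ratios scaling). In control replicate 3 the list's median lay 0.64 above the other controls. Of 25 mitochondrial chaperones and proteases, 3 rose and 1 fell, with 3 and 0 adjusted over the list alone (camera adjusted p = 0.593, 6 and 5 without control replicate 3, 5 and 1 without control replicate 2, and 3 and 4 with median-of-ratios scaling). HSPA9 rose 2.17-fold, GRPEL2 2.36-fold and DNAJA3 2.8-fold, while HSPD1 stood at 250 ± 7.27 with fisetin and 277 ± 91.9 RPKM in control (limma adjusted p = 0.825, and 0.02 and lower with fisetin without control replicate 3). Of 18 genes of mitochondrial dynamics and biogenesis, 2 rose, MFN2 1.79-fold and ESRRA 1.45-fold, with 0 adjusted over the list alone, 4 without control replicate 3, 1 without control replicate 1 or 2 and 0 without any 1 of the fisetin libraries or with median-of-ratios scaling (camera adjusted p = 0.835). In this list 1 gene fell without control replicate 3. HSPE1 was the chaperone gene that fell, from 3.77 ± 0.707 in control to 2.35 ± 0.255 RPKM with fisetin (limma adjusted p = 0.0496). Without control replicate 1 or any 1 of the fisetin libraries 0 chaperone genes fell.

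Of 27 targets of the oxidative stress factor NFE2L2, 9 rose and 5 fell over all genes, and 10 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.763). HMOX1 rose most, from 28.3 ± 8.48 to 378 ± 35 RPKM. OSGIN1 rose 11.4-fold, the cystine transporter gene SLC7A11 9.84-fold and GCLM, of glutathione synthesis, 3.43-fold. NQO1 rose 1.67-fold (limma adjusted p = 0.0264, and 0.0985 with median-of-ratios scaling). The members that fell, chosen after their values were seen, included GPX4, CBR1, TALDO1 and TKT, with GPX4 2.77-fold lower. They numbered 0, 0, 0 and 2 without fisetin replicates 1, 2 and 3 and control replicate 1. Of 10 targets of the aryl hydrocarbon receptor, 5 rose and 1 fell, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.137). This list also holds the receptor gene AHR itself, which was among the 5 that rose. EREG rose 5.46-fold and CYP1B1 was 2.69-fold lower, and CYP1A1 stood below the filter at 0.45 ± 0.273 with fisetin and 0.172 ± 0.125 RPKM in control. The risen members numbered 1 without any 1 of the fisetin libraries, 2 and 3 without control replicates 1 and 2, and 2 with median-of-ratios scaling, and 0 fell without control replicate 1 or any 1 of the fisetin libraries.

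Among 23 p53 targets, 10 rose and 0 fell over all genes and adjusted over the list alone (median 0.35 above all genes, camera adjusted p = 0.00417, adjusted p = 0.2 with an estimated correlation). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 9.32 ± 0.9 to 50.6 ± 3.15 RPKM, and the death receptor gene TNFRSF10B rose 5.75-fold. SESN2 and GADD45A, also in this list, are stress genes with other known regulators. The count was 5, 5 and 6 without fisetin replicates 1, 2 and 3. Of 25 apoptosis regulators, 9 rose and 2 fell, with 11 and 2 adjusted over the list alone (camera adjusted p = 0.0406, adjusted p = 0.335 with an estimated correlation, and 0.0632 with median-of-ratios scaling). PMAIP1 rose 4.78-fold and CASP9 4.07-fold, both promoters of cell death, while BCL2A1, which opposes it, rose 3.68-fold. BID and BIRC5, chosen after their values were seen, fell, and 0 fell without fisetin replicate 1 or 2 or control replicate 1 and 1 without fisetin replicate 3.

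**Figure D3:**
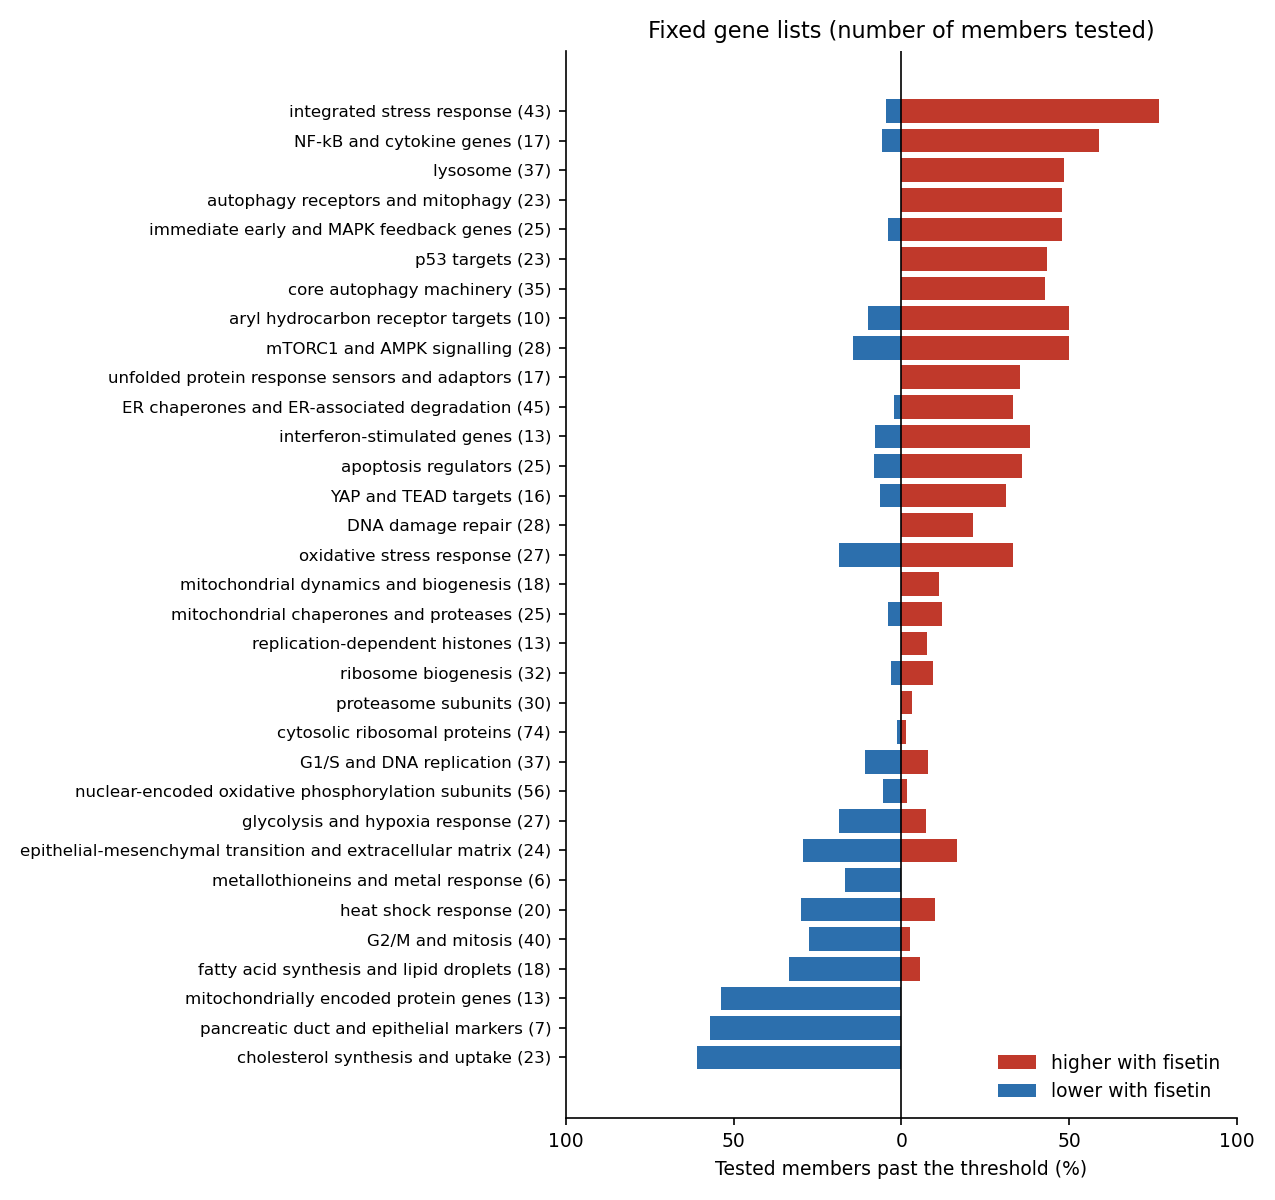
Percent of the tested members of each fixed list that were called higher (right, red) or lower (left, blue) with fisetin on the deposited scale, with the number tested in brackets. The integrated stress response has 33 of 43 members higher and cholesterol synthesis and uptake 14 of 23 lower.

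Of 23 genes of cholesterol synthesis and uptake, 0 rose and 14 fell over all genes, and 1 rose and 15 fell adjusted over the list alone. The median lay at -1.07 relative to all genes (camera adjusted p = 1.15e-09, adjusted p = 0.0804 with an estimated correlation). FDFT1, of squalene synthesis, was 3.15-fold lower, DHCR7 3.09-fold and MSMO1 2.32-fold. The count was 8 and 9 without fisetin replicates 2 and 3, and 1 rose without control replicate 3. Of 18 genes of fatty acid synthesis and lipid droplets, 1 rose and 6 fell, with 2 and 6 adjusted over the list alone (median -0.59 relative to all genes, camera adjusted p = 0.000415, adjusted p = 0.2 with an estimated correlation). ACACA, the first enzyme committed to fatty acid synthesis, was 3.13-fold lower, and GPAM, chosen after its values were seen, was the member that rose, with 3 rising without control replicate 3 and 0 without any 1 of the fisetin libraries.

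Among 40 genes of G2/M and mitosis, 1 rose and 11 fell over all genes and adjusted over the list alone (median -0.59 relative to all genes, camera adjusted p = 2.89e-07, adjusted p = 0.313 with an estimated correlation). The kinesin gene KIF20A was 4.82-fold lower, the cyclin gene CCNB1 3.18-fold, the kinase gene PLK1 3.6-fold and CDC20 2.38-fold. The count was 23 without control replicate 3, 7, 6 and 7 without fisetin replicates 1 and 2 and control replicate 1, and 17 with median-of-ratios scaling. The risen members numbered 2 without control replicate 3, and 0 when any other library was left out or with median-of-ratios scaling. Of 37 G1/S and replication genes, 3 rose and 4 fell, with 1 and 2 adjusted over the list alone (camera adjusted p = 0.167). Without control replicate 3 the list was called lower (adjusted p = 0.0086), with 6 rising and 11 falling. Without any 1 of the fisetin libraries or control replicate 1, 1 rose and 2 or 3 fell, without control replicate 2, 5 rose and 2 fell, and with median-of-ratios scaling 1 rose and 6 fell. RPA2 rose 2.11-fold, while UHRF1 was 2.85-fold lower, MCM7 2.02-fold and CCNE1 1.6-fold.

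**Figure D4:**
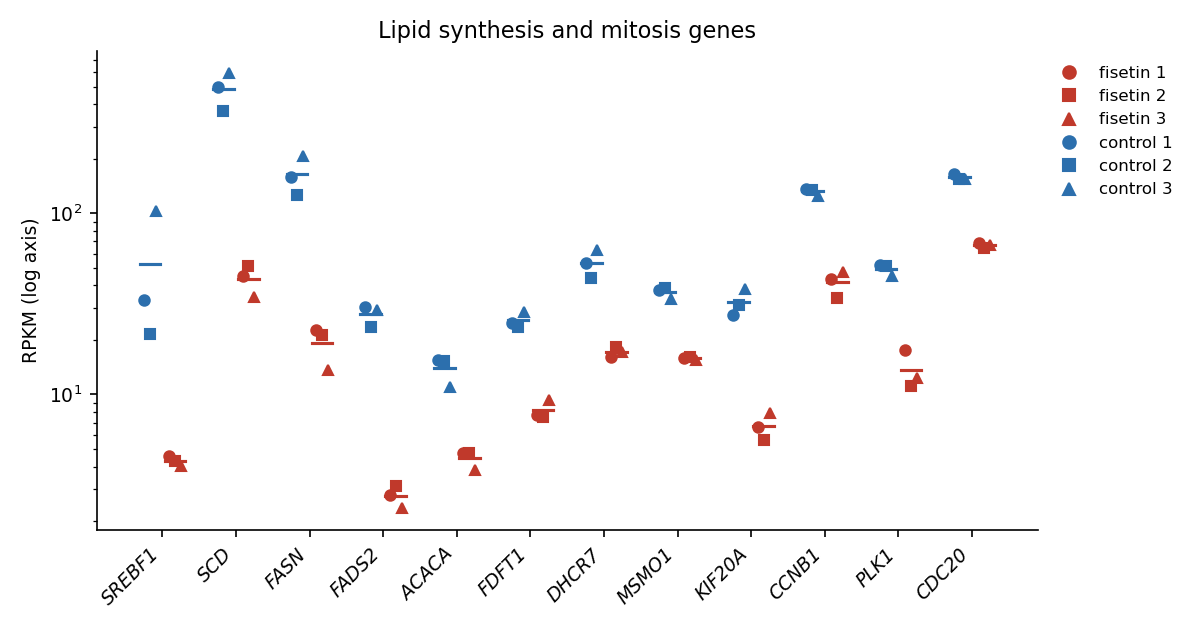
RPKM on a log axis of 8 lipid synthesis and 4 mitosis genes in each library, with colour for the group, marker for the replicate and a line at the group mean (n = 3 each). All 12 genes lie lower in each fisetin library than in each control library, with PLK1 at means of 13.7 and 49.4 RPKM.

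Of 27 genes of glycolysis and the hypoxia response, 2 rose and 5 fell over all genes, and 2 rose and 4 fell adjusted over the list alone (median -0.69 relative to all genes, camera adjusted p = 0.000808, adjusted p = 0.586 with an estimated correlation). Control replicate 3 lay 0.80 above the other controls in this list's median, with GAPDH, a gene chosen after its values were seen, at 1518 RPKM against 625 and 513. LDHA was 2.52-fold lower and PKM 2.06-fold lower, while NDRG1 rose 2.1-fold and VEGFA 1.66-fold (limma adjusted p = 0.0245, and 0.0881 with median-of-ratios scaling). Leaving out control replicate 3 moved the list's median to -0.40 relative to all genes (camera adjusted p = 0.0189). The members that fell numbered 11 without that library, 11 without control replicate 2, 2 without control replicate 1 and 2, 1 and 1 without fisetin replicates 1, 2 and 3. Those that rose numbered 4 without control replicate 3 and 1 when any other library was left out or with median-of-ratios scaling. Among 20 heat shock genes, 2 rose and 6 fell over all genes and adjusted over the list alone (median -0.39 relative to all genes, camera adjusted p = 0.00699, adjusted p = 0.284 with an estimated correlation). The chaperone genes HSP90AB1 and HSPA1A were 1.86-fold and 1.74-fold lower and FKBP4 2.08-fold, while DNAJB4 rose 2.45-fold, and 11 fell without control replicate 3 and 2, 2, 3 and 2 without fisetin replicates 1, 2 and 3 and control replicate 1. The list's median lay at -0.61 relative to all genes without control replicate 3 and -0.26 without control replicate 2. In this list 1 gene rose without fisetin replicate 1 or 2 or control replicate 1 or 2, and 1 with median-of-ratios scaling.

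Of 25 immediate early and MAPK feedback genes, 12 rose and 1 fell over all genes and adjusted over the list alone (median 0.56 above all genes, camera adjusted p = 0.00531, adjusted p = 0.2 with an estimated correlation). MAFF rose 11-fold and FOSL2 3.66-fold. The median lay 0.92 above all genes without control replicate 3. The risen members numbered 21 without that library, 7, 7 and 6 without fisetin replicates 1, 2 and 3, and 8 with median-of-ratios scaling. Of 17 NF-kB and cytokine genes, 10 rose and 1 fell by either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.0607, 0.0201 with median-of-ratios scaling, and 0.0442, 0.0395 and 0.0189 without fisetin replicates 2 and 3 and control replicate 3). CXCL8 rose from 0.0843 ± 0.039 to 3.86 ± 0.741 RPKM, CCL20 from 0.128 ± 0.0428 to 3.02 ± 0.444 RPKM and PTGS2 from 0.112 ± 0.0713 to 3.24 ± 1.53 RPKM, all low in control, and RELB rose 3.32-fold. In this list 0 genes fell when any library other than control replicate 3 was left out. Of 28 genes of mTORC1 and AMPK signalling, 14 rose and 4 fell over all genes and adjusted over the list alone (camera adjusted p = 0.218). PRKAG1 and RRAGC rose 2.32-fold and 2.56-fold, while DEPTOR, which binds the mTOR kinase, was 5.51-fold lower, and 8, 7 and 8 rose without fisetin replicates 1, 2 and 3, with 2 falling in each case.

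Of 24 genes of epithelial-mesenchymal transition and extracellular matrix, 4 rose and 7 fell, with 4 and 9 adjusted over the list alone (median -0.33 relative to all genes, camera adjusted p = 0.0251, adjusted p = 0.2 with an estimated correlation, 0.0781 with median-of-ratios scaling and 0.0606 without fisetin replicate 3). COL1A1 fell from 33.4 ± 4.3 to 2.85 ± 0.348 RPKM and MMP14 was 3.83-fold lower, while CTGF rose 2.94-fold and MMP1 rose from 0.137 ± 0.0944 to 4.04 ± 0.986 RPKM. The members that fell numbered 11 without control replicate 3 and 4 without fisetin replicate 1 or 2, and those that rose 7 without control replicate 3 and 2 without fisetin replicate 2. CYR61, chosen after its values were seen, also rose, 2.3-fold. All 7 tested duct and epithelial markers gave 0 risen and 4 fallen members, and 5 fallen adjusted over the list alone (median -1 relative to all genes, camera adjusted p = 9.29e-05, adjusted p = 0.247 with an estimated correlation). SOX9, a transcription factor of duct cells, fell from 72.8 ± 13.1 to 13.7 ± 1.43 RPKM, and MUC1, KRT8 and KRT18 were 3.83-fold, 2.82-fold and 1.75-fold lower. The list's median lay 0.48 higher in control replicate 3 than in the other controls. Of 16 YAP and TEAD targets, 5 rose and 1 fell, with 7 and 2 adjusted over the list alone (camera adjusted p = 0.414). ANKRD1 rose from 0.136 ± 0.103 to 5.74 ± 2.13 RPKM and LATS2 2.23-fold. WWTR1, a paralogue of YAP that the list also holds, was 2.25-fold lower. The risen members numbered 3 without fisetin replicate 1 or 2 or control replicate 1, and 3 with median-of-ratios scaling, and 2 fell without control replicate 3 or with median-of-ratios scaling. In control replicate 3 the list's median lay at -0.66 relative to the other controls. Without that library it lay at -0.19 relative to all genes (camera adjusted p = 0.972), against 0.12 with it.

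Of 74 cytosolic ribosomal protein genes, 1 rose and 1 fell over all genes, RPL26 and RPS23, and 0 rose and 1 fell adjusted over the list alone. The list lay at -0.27 relative to all genes (camera adjusted p = 0.00531, adjusted p = 0.847 with an estimated correlation). Its direction turned without control replicate 3 (0.04 above all genes, camera adjusted p = 0.391). There 20 rose and 2 fell, while of all 12396 tested genes 4363 rose and 2039 fell. In control replicate 3 the list's median lay 0.87 above the other controls. The list lay at -0.52 relative to all genes without control replicate 2. When any other library was left out 0 rose, and with median-of-ratios scaling 0 rose and 2 fell. Ribosomal protein genes have many pseudogenes, so their values are uncertain. Of 32 ribosome biogenesis genes, 3 rose and 1 fell, with 2 and 0 adjusted over the list alone (camera adjusted p = 0.896). RRN3 and RRP12 rose 2.4-fold and 2.74-fold, while BOP1 was 1.5-fold lower. Without control replicate 3, 5 rose and 9 fell, and without any 1 of the fisetin libraries 1 rose and 0 fell. Without control replicate 1 or 2, 0 fell. With median-of-ratios scaling 2 rose and 3 fell. In control replicate 3 the list's median lay at -0.74 relative to the other controls, and without that library it lay at -0.18 relative to all genes, against 0.06 with it and -0.02 without fisetin replicate 1 or 2.

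The remaining lists were not called by camera at the preset correlation. Of 28 DNA repair genes, 6 rose, among them BARD1 1.82-fold (adjusted p = 0.0818 with median-of-ratios scaling), and 0 adjusted over the list alone (camera adjusted p = 0.218), and 0.0391 for camera without control replicate 2. Without control replicate 3, 10 rose and 3 fell, and the list's median lay at -0.09 relative to all genes (camera adjusted p = 0.94), against 0.14 with it. That library lay at -0.89 relative to the other controls in this list. The risen members numbered 1, 0, 0 and 2 without fisetin replicates 1, 2 and 3 and control replicate 1, and 1 with median-of-ratios scaling. Of 13 interferon-stimulated genes, 5 rose and 1 fell over all genes and adjusted over the list alone (camera adjusted p = 0.771), with 0 rising without any 1 of the fisetin libraries or control replicate 1, 3 without control replicate 2 and 2 with median-of-ratios scaling, and 2 falling without control replicate 2 or 3. STAT2 rose 1.84-fold and IRF1 2.61-fold, and IFIT1 was 4.53-fold lower. Of 6 metallothionein and metal genes, 0 rose and 1 fell, with 3 falling adjusted over the list alone (camera adjusted p = 0.0522, and 0.0198 and 0.0442 without fisetin replicates 1 and 2). The fallen member was MT1A, chosen after its values were seen. In this list 0 fell without fisetin replicate 2 or control replicate 1, 1 rose and 2 fell without control replicate 2, 1 rose and 3 fell without control replicate 3, and 3 fell with median-of-ratios scaling. MT2A stood at 85 ± 11 with fisetin and 129 ± 28.3 RPKM in control (limma adjusted p = 0.0532, and 0.0257 without control replicate 3). Of 30 proteasome genes, 1 rose, PSMC4 1.34-fold, and 0 adjusted over the list alone (camera adjusted p = 0.0999, 0.00971 and lower with median-of-ratios scaling, and 0.0441 and 0.0456 without fisetin replicate 3 and control replicate 3, where 4 rose and 7 fell). None rose when any other library was left out, and with median-of-ratios scaling 0 rose and 4 fell. Of 13 replication-dependent histone genes, 1 rose, HIST1H4H, chosen after its values were seen, by either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.73). Without control replicate 3, which lay 0.79 above the other controls in this list, 8 rose, and without control replicate 2 the list's median lay at -0.04 relative to all genes, against 0.18 with it.

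Markers of other cell types were few. Of the leukocyte markers 1 passed the filter, CD8A, at 1.89 ± 0.283 with fisetin and 1.28 ± 0.566 RPKM in control (limma adjusted p = 0.216, and 0.0303 without control replicate 3). Of the erythroid and endothelial markers 0 passed, and 0 of the pancreatic acinar and endocrine markers. The 3 tested markers of fibroblasts and stellate cells, COL1A1, COL3A1 and THY1, fell, COL3A1 7.16-fold and THY1 3.37-fold lower with fisetin.

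Over all lists, 286 of 851 distinct tested members changed, 290 with each list adjusted over the list alone. This share is close to the 31.7% of all tested genes that changed, so members of the lists together were called about as often as other genes. Counts of single lists in the main fit are to be read against 2758 risen and 1171 fallen of the 12396 genes tested. Those of another fit are to be read against all genes of that fit. Without control replicate 3, 4363 rose and 2039 fell. Without fisetin replicates 1, 2 and 3, 1339, 1117 and 1320 rose and 557, 534 and 587 fell. Without control replicates 1 and 2, 1517 and 2475 rose and 666 and 1181 fell. With median-of-ratios scaling 1535 of 12342 rose and 1680 fell. The count of changed list members was 165, 151, 166 and 185 without fisetin replicates 1, 2 and 3 and control replicate 1, and 478 without control replicate 3. Camera called 16 of the 33 lists at the preset correlation and 0 with an estimated correlation, where 8 had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 20.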

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

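Tests chosen only after the results were seen are the pseudocounts, array weights, removal of the GC and length trend and upper-quartile scaling for the lists. The others are TMM scaling of all genes on RPKM, and the counts of list members by scaling and without single libraries. The design had named TMM for its count-based main test, which was not run. On RPKM, TMM gave 3208 changed genes, 48.8% of them higher, against 70.2% on the deposited scale. Other planned fits that need read counts were not run either, except limma-voom, which used the recovered reads and gave 3966 changed genes. The planned scaling to library size is the deposited one.

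The number of changed genes was between 1651 (without fisetin replicate 2) and 6402 (without control replicate 3) when 1 library was left out, with 1117 to 4363 higher and 534 to 2039 lower. Without control replicate 3, 3925 of the 3929 calls were kept. No gene called on the deposited scale was called in the opposite direction in any alternative. Median-of-ratios, upper-quartile, TMM without mitochondrial and top genes, and TMM scaling gave 1535, 1439, 1560 and 1566 higher genes, and upper-quartile scaling 1839 lower. A value of at least 5 left fewer genes tested, with 2616 changed and 1781 higher. An adjusted p under 0.01 left 1443, with 992 higher and 451 lower, and a test against a 1.5-fold change left 428. Genes changed at least 2-fold, by the log2 fold change of each fit, numbered 2210 with limma-voom and 2126 with a pseudocount of 0.1. Array weights, whose estimation did not converge, gave 9308 changed, 6015 higher and 3293 lower. With the GC and length trend removed 2151 were lower, and without control replicate 3 as well, 6623 changed with 3243 lower. An adjusted p under 0.01 and a test against a 1.5-fold change leave fewer calls because they are stricter. A smaller pseudocount understates the change of low genes less, which raises the count of 2-fold changes. The cause of the other shifts was not tested unless stated.

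Camera called 0 lists with an estimated correlation and 14 to 19 in its other alternatives, and fry called 20. With an estimated correlation all 16 called lists lost their call, though not every estimate lay above the preset 0.01. It was 0.0102 for core autophagy and 0.00556 for cholesterol synthesis and uptake, and 0.668 for glycolysis and hypoxia. The unadjusted camera p of core autophagy still went from 0.000145 to 0.0193. A higher correlation between genes therefore cannot account for each lost call. With an estimated correlation camera uses the residual degrees of freedom of the few libraries, and with a preset one those of the genes. For core autophagy, at nearly the same correlation, this difference raised p. Its share in the other lost calls was not tested. Leaving out the estimated correlation and fry, 395 values of single lists by camera at the preset correlation remain. Of these 371 kept their call, 7 lost it, 16 gained it and 1, of a called list, turned direction. That was the list of cytosolic ribosomal proteins, at 0.040 relative to all genes without control replicate 3 and -0.52 without control replicate 2. List members called numbered 151 to 478 when 1 library was left out. Of 2454 values of called named genes, 2217 kept the call and 237 lost it. With the replicate number as a block 3321 genes changed. Deviations of same-numbered libraries correlated at 0.21, 0.03 and 0.21, so not every pair passed 0.1 and the numbers were not taken as pairs. Fisetin replicate 2 and control replicate 2 did not correlate best with their own number. Simulated 1.5-fold changes were not detected, but far fewer genes changed there than in the real fit. The real fit called some smaller ratios, such as ATP5F1A at 1.36-fold lower.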

Other observations

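The gene families below, the tests of a mislabelled library, of glycolysis and hypoxia genes and the other lists in control replicate 3, of the scaling and of the SNHG genes were chosen only after the results were seen.

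Families of genes that share the start of their symbol were compared with all tested genes by a one-sided Fisher's exact test in each direction, over 268 families with at least 6 tested members (536 tests). The one-sided form replaced a two-sided one after its first output was seen. Members are not independent, so these p-values are too small. Of 12 collagen genes 9 fell and 0 rose (adjusted p = 2.64e-05), among them COL11A1, from 77.3 ± 15.6 to 17.1 ± 2.29 RPKM, and COL5A2, from 238 ± 20 to 81 ± 13.3 RPKM (SD, n = 3). Of the HOXB and HOXC clusters, 7 of 9 and 7 of 8 tested genes fell, such as HOXB8 from 21.7 ± 4.27 to 4.83 ± 0.351 RPKM. Of 8 SOX genes 6 fell, SOX4 from 16.4 ± 0.985 to 4.35 ± 0.995 RPKM, of 6 cadherin genes 5 fell, and of 7 WNT genes 5 fell and 1 rose, with WNT7B, the genes here being chosen after their values were seen, falling from 13.3 ± 0.809 to 2.85 ± 0.645 RPKM and WNT9A rising from 5.37 ± 0.429 to 11.7 ± 1.19 RPKM. The WNT family was not called without control replicate 3 (adjusted p = 0.102), nor were the WNT, SOX and cadherin families with the GC and length trend removed (0.118, 0.0594 and 0.0721).

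Of 364 zinc finger genes with the ZNF symbol, 192 rose and 6 fell, and 119 rose and 7 fell with median-of-ratios scaling. ZNF550 rose from 2.95 ± 0.112 to 10.8 ± 0.826 RPKM, and ZNF608 fell from 9.67 ± 0.62 to 2.78 ± 0.35 RPKM. Of 16 DUSP genes, mostly phosphatases, 10 rose (adjusted p = 0.0365, and 0.204 with the GC and length trend removed). Of 61 RNF genes 29 rose and 5 fell, and 13 rose and 6 fell with median-of-ratios scaling, where the family was not called (adjusted p = 0.613). Nor was it called without control replicate 3 (0.102) or with the GC and length trend removed (0.429).

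Control replicate 3 stood apart from the other control libraries. A mislabelled fisetin library would lie near the fisetin mean, but over the 1328 genes called at least 2-fold changed in the fit without that library its median position was 0.0684, where 0 is the mean of the other controls and 1 that of fisetin. GC content and length as the whole cause were argued against, since after removal of their trend, with 36.2% of the variance, the SD of its difference from the other controls was 2.43 times that of control replicate 1 minus 2 (2.76 before). After that removal the median difference of the glycolysis and hypoxia genes was 1.07, at percentile 100 of 10000 random lists, but 14 of 33 lists lay in the outer 5% of their random lists, cytosolic ribosomal proteins at 0.85, interferon-stimulated genes at 0.61, oxidative phosphorylation at 0.53, ribosome biogenesis at -0.60 and G1/S genes at -0.53 among them, so the shift may lie partly in glycolysis and hypoxia genes but is not particular to that list. Beyond the gene lists no biological explanation was tested, and a difference in culture or library preparation stays open.

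On the deposited scale 70.2% of calls were higher, and with median-of-ratios scaling 47.7%. That scaling sets the median log2 fold change near 0 (0.01, against 0.20), which brings the share near an even split whatever the source of the excess. The test therefore does not show whether scaling each library to its total was the source. Without a spike-in this and a change in total RNA with fisetin cannot be told apart.

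Fold changes fell with the GC content of the transcript, with Spearman's rho of -0.268 across genes, which are not independent. Without control replicate 3 rho was -0.0757, so that library is a candidate source of the trend. The median log2 fold change was 0.39 for genes under 40% GC and -0.11 over 60% GC, and 0.23 and 0.09 without it.

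A hypothesis on the SNHG genes, noncoding hosts of small nucleolar RNAs, was that they rose more than noncoding transcripts in general. Of 17 tested, 9 rose and 0 fell, SNHG1 from 11.2 ± 1.41 to 39.8 ± 3.78 RPKM. Their median log2 fold change of 0.97 lay at percentile 100 of 10000 random lists of noncoding genes matched on mean expression. The family was picked for its high median among many, and the comparison of all 268 families did not call it (adjusted p = 0.246, and 0.00592 with median-of-ratios scaling), so this percentile does not decide the question.

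The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 3929 changed genes, 2758 in the larger and 1171 in the smaller direction and 1384 changed at least 2-fold, each in 1 of the 10 splits, and the highest other split gave 0. For the lists called by camera, 2 of 10 splits gave as many, 16 in the real split and 17 in the highest other. The other splits called 8 to 17, so camera at the preset correlation calls lists here between groups that mix both treatments. Each other split sets 2 fisetin libraries and 1 control library against 1 and 2, so part of the fisetin difference remains between its groups. The rest lies within them and widens their spread. Neither the 0 genes nor the lists of these splits therefore show what chance alone gives.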
